A study of Caenorhabditis elegans with 2 samples.

How the data were processed

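Chromatin from whole L1 larvae was immunoprecipitated with an antibody against the GFP tag of NHR-71 in 2 biological replicates, fragmented by sonication and sequenced, per the labels. The labels call the replicates biological, and both carry the same strain and stage. The authors deposited, for each of the ce11 and ce10 genome builds, 4 peak lists in the narrowPeak format: 1 list per replicate, 1 list from the pooled replicates, and the set of peaks that passed their IDR threshold. Per the submitters' file list, replicate and pooled lists were made from alignments of the immunoprecipitated library and a control and were meant as input to IDR, and the IDR set was derived from the replicate lists and the pooled list. The aligner, the peak caller, the IDR threshold and the scale of the signal are not given in the sources used here. The control library was not analysed here.

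In each list the authors deposited a signal value and a -log10 (q) value per peak, together with the offset of the summit. Only the signal was used to rank peaks, since all 8540 IDR peaks carry the same deposited -log10 (q) of 4.28454. Each replicate or pooled list ends at 30000 positions and so includes background. The IDR set on ce11 is the same as the 8540 positions of highest signal in the pooled list. An interval can hold several summits (231 of the IDR peaks repeat an interval), and each summit was kept as a peak. Where a summit offset equals the peak width, the last base of the peak was used. Because the lists hold no read counts, read depth and its counting error are unknown; intervals printed for shares cover counting of peaks or genes only. The number of replicates, 2, limits the precision of the values set between them.

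Coordinates are on ce11 (WBcel235) and 1-based. Genes were taken from Ensembl release 115 and sequence from the RefSeq copy of the same assembly. The analysis used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9. Promoter windows ran from 1000 bp upstream to 200 bp downstream of the annotated gene start of 19973 protein-coding genes on nuclear chromosomes, and a gene counted as having a promoter peak when a summit lay in its window. Many nematode genes are trans-spliced, so the annotated start can differ from the start of transcription. For values per replicate, each replicate list was reduced to its 8540 positions of highest signal, and mean ± SD refers to both replicates.

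Places of summits, overlap of replicates and distance to non-coding genes were tested against 1000 circular shifts of the peaks, 1 random offset per chromosome. These shifts permute positions, so their p-values are permutation p-values, two-sided except for the overlap, which was tested one-sided, and a summit inside a peak of the other replicate counted as shared. Gene lists and chromosome classes were tested by two-sided Fisher's exact tests, and matched random lists gave two-sided permutation p-values. For sequence words, the 100 bp centred on each summit was compared with windows 300 bp to each side by a two-sided exact McNemar test, and the larger of the p-values against both flanks was kept. Signal in promoters and elsewhere was compared by a two-sided permutation test with 100000 resamples. Benjamini-Hochberg adjustment was applied over 42 gene lists, 22 fixed words, 2080 words of 6 bases and 10 non-coding types separately, with a threshold of 0.05. Lists or types under 5 genes were left out.

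Groups, tests, gene lists, words, the alternatives and the rule for named genes were set before the data were examined. The text names protein-coding genes at the 25 strongest IDR peaks, or the nearest gene start for a peak in no window. It names the 4 members of highest signal in each list above background, the 2 in each list below it, at most 5 members of the nuclear receptor and GATA lists, and nhr-71 and unc-119 whatever their values. The members of the chemoreceptor list that this rule takes are not reported here. Of the words of 6 bases past the threshold it names the 5 with the largest ratio among those in at least 2% of peaks. Alternatives included promoter windows of 500 and 2000 bp, the 4270 IDR peaks of higher signal, each replicate list alone, summit distances of 100 and 50 bp, the ce10 lists, 10000 random gene lists matched on upstream distance and orientation, and, in place of the flanks, background windows at other promoter positions matched on GC content, which changes place and GC content together. A rotation of the bound genes along the gene order of each chromosome was added after the data had been seen.

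The tests on gene lists, places, overlap, words, non-coding types and signal were tested on simulated data. With random genes bound, 2 of 100 simulations over 19973 genes called any gene list, and with an odds ratio of 3 planted in 3 lists, 97.7% of these lists were called with a median odds ratio of 2.88. Bound genes were drawn independently in these simulations. They therefore do not give the error rate where neighbouring genes share a peak. For 8000 random peaks the promoter share was 1.01 times that under shifts. A word planted in 5% of windows was found in 5.73%, and 0 words of 6 bases were called when the windows were put in random order. Peaks placed at 29.9% of tRNA genes were called with an adjusted p of 0.02, and the share found near a peak, random peaks included, was 41.3%.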

Results

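Chromatin immunoprecipitation followed by sequencing was used to map where NHR-71, a nuclear hormone receptor of the nematode Caenorhabditis elegans, is found on the genome in first-stage (L1) larvae. The worms carried an integrated transgene that makes NHR-71 fused to green fluorescent protein, and an antibody against that tag was used. Larvae were hatched without food, which holds them at the start of L1, and were collected 6 h after this synchronization as whole hermaphrodites. There was 1 group with 2 biological replicates, so the comparisons are between the replicates and between classes of genes, regions and sequences within the peak set. Each replicate list held 30000 ranked positions, and the set that passed the authors' test of reproducibility between replicates (irreproducible discovery rate, IDR) held 8540 peaks on the ce11 build. Read depth is unknown because the lists hold no read counts. Signal values are the authors' own, and they are used here only to rank and describe peaks within a list.

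The strongest peaks of both replicates lay at the same places, led by the promoter of rpl-3, which encodes a protein of the large ribosomal subunit. This peak, on chromosome III from 3867264 to 3867872, had a signal of 6143 in the IDR set and ranked 1 in both replicate lists. Of the 8540 strongest peaks of replicate 1, 7199 had their summit inside a top peak of replicate 2, which is 84.3% (95% Wilson interval 83.5% to 85.1%). In the opposite direction the share was 84.9% (84.2% to 85.7%). Permutation of the positions by circular shifts along each chromosome gave 3.02% ± 0.204 and 3.08% ± 0.212 (mean and SD of 1000 shifts; one-sided p = 0.001, the smallest that the shifts can give). With the full lists of 30000 positions, peaks of both replicates covered 8426 of the 8540 IDR summits, or 98.7%. These peaks are not independent replicates. They come from the IDR set, which equals the 8540 positions of highest signal in the pooled list. Across them Spearman's rho between the replicates' signals was 0.895. The log2 ratio of replicate 2 to replicate 1 had a median of -0.12 and an SD of 0.47.

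**Figure D1:**
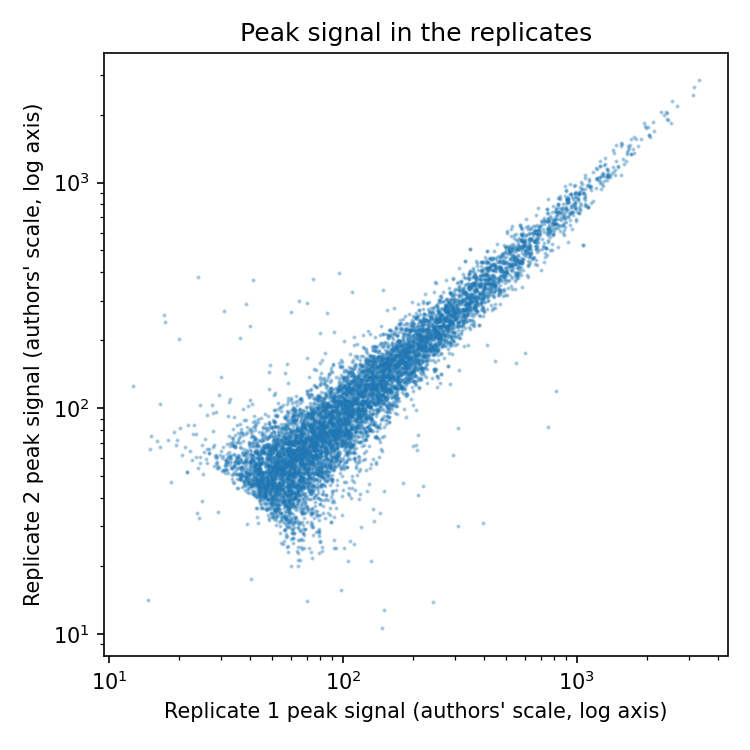
Signal of each IDR peak in replicate 1 (x axis) and replicate 2 (y axis), both on log axes in the authors' scale, for the 8426 IDR summits that lie in a peak of both replicates. Points form 1 band along the diagonal that is narrower at high signal, with a Spearman's rho of 0.895.

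Promoters held more of the IDR peaks, and coding exons fewer, than shifted positions did. Summits within 1000 bp upstream to 200 bp downstream of an annotated protein-coding gene start made up 41.6% of the set (3550 of 8540; 95% Wilson interval 40.5% to 42.6%). Circular shifts placed 21.2% ± 0.537 there, so the observed share was 1.963 times that under shifts. Coding exons outside these windows held 161 summits, or 1.89% (1.62% to 2.20%), against 19.97% ± 0.575 under shifts. Introns held 23.9% against 30.6% ± 0.800, untranslated and other exons 2.46% against 3.10% ± 0.197, and the remaining sequence, mostly intergenic, 30.2% against 25.2% ± 0.646. The two-sided p was 0.002, the smallest that 1000 shifts can give, for each place except the untranslated and other exons, where it was 0.004. Taken from the replicate lists, cut to as many peaks, the promoter share was 42.3% ± 0.0580 (SD, n = 2) and the coding exon share 1.99% ± 0.116 (SD, n = 2). Among the 4270 IDR peaks of higher signal the coding exon share was 0.913% and that of untranslated and other exons 1.55%, and with windows from 2000 bp upstream the remaining sequence held 20% of summits. With windows from 500 bp upstream promoters held 33.2% and the remaining sequence 37.5%, so their order turned. Within promoters the median summit lay 202 bp upstream of the nearest gene start, with quartiles at 416 bp and 94.0 bp upstream. Of the promoter peaks, 824 (23.2%) lay in windows of genes on both strands. Such a peak cannot be given to either gene of a divergent pair.

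Peaks in promoters were also stronger than peaks elsewhere. The median signal was 241 (quartiles 138 and 472) over the 3550 promoter peaks and 171 (quartiles 114.8 and 309) over the 4990 other peaks. The difference of the medians was 69.3 ± 5.68 (bootstrap SE), and the two-sided permutation test gave p = 1e-05, the smallest its 100000 resamples allow. The ratio of the medians was 1.405 in the IDR set, 1.35 in replicate 1 and 1.35 in replicate 2.

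Of the 25 strongest IDR peaks, 16 lay in the promoter window of a protein-coding gene, and several of these genes belong to the translation machinery. Apart from rpl-3, they included the ribosomal protein genes rpl-35, rpl-20 and rpl-15 (signals 4429, 4328 and 4327), and iff-2, which encodes a translation initiation factor (3343). The peaks of rpl-20, rpl-15 and iff-2 also lay in the windows of Y17G9B.5, K11H12.8 and F54C9.14, in that order. None of these shared peaks can be given to 1 gene, and the start of Y17G9B.5, 175 bp away, was nearer than that of rpl-20. The second strongest peak, on chromosome III from 10758965 to 10759636 with a signal of 5790, lay in the windows of both tasp-1 and K01G5.10. The promoter peak of puf-9, a Pumilio-family RNA-binding protein gene, reached 4871 on chromosome X from 5840906 to 5841609. That of cdc-48.1, which encodes an AAA ATPase, reached 4812 on chromosome II from 10563308 to 10563830. The remaining genes with a window at one of these peaks were nhl-2 and tag-340, egg-5, epn-1, tos-1, H41C03.3, drr-2 and set-16, cox-5A, and H12C20.7 and nhr-68. Their peaks had signals from 3250 to 4451. The other 9 peaks lay in no window. The strongest of these was on chromosome III from 12612348 to 12613028 (signal 5590) in an intron of Y111B2A.12, 3348 bp from its start. A pair of them lay in introns of pqn-41, of which the first was 18277 bp from the start of F53A3.1, its nearest gene start, and the second 15449 bp from the start of pqn-41. An intron of epg-9, 1027 bp from its start, and an intron of W06H8.6, 2335 bp from its start, held 1 peak each. Outside gene bodies, the nearest starts were those of cmd-1 at 4778 bp, sup-26 at 1992 bp, hif-1, the hypoxia-inducible factor gene, at 1987 bp, and T04C4.3 at 2774 bp. All 25 peaks ranked 28 or better in replicate 1 and 31 or better in replicate 2.

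Genes for basic metabolism and protein synthesis had promoter peaks far more often than other genes, and genes for chemosensation and the cuticle less often. A promoter peak was found at 4152 of 19973 protein-coding genes (20.8%), and the replicate lists gave 21.1% ± 0.0425 (SD, n = 2). Of 42 gene lists, 16 had a higher share than all other genes and 7 a lower share (two-sided Fisher's exact test, Benjamini-Hochberg adjusted over the 42 lists, threshold 0.05).

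The highest shares were in the citric acid cycle and the cytosolic ribosome. Citric acid cycle genes had a promoter peak in 23 of 26 cases (88.5%; 95% exact interval 69.8% to 97.6%; adjusted exact p = 1.56e-12), led by dld-1 (signal 1959), aco-2 (1228), icl-1 of the glyoxylate shunt (1097) and sdha-1 (954). The interval at icl-1, from 723877 to 728420 on chromosome V, covers the whole gene. Its width of 4544 bp is the largest in the IDR set, where the median is 420 bp. Cytosolic ribosomal protein genes had one in 68 of 79 cases (86.1%; 76.5% to 92.8%; adjusted exact p = 4.17e-34), and the share was also 86.1% in each replicate list. Oxidative phosphorylation genes had one in 50 of 72 cases (69.4%; adjusted exact p = 1.08e-17), with replicate values of 67.4% ± 2.95 (SD, n = 2). Their strongest peaks were at cox-5A (3283), cox-5B (1758), atp-1 (1662) and nduc-2 (1578). Among translation factors the count was 32 of 43 (74.4%; adjusted exact p = 4.64e-13), and besides iff-2 the elongation factor genes eef-1A.2 (1856), eef-1A.1 (1843) and eef-1G (1837) had the highest signals. Aminoacyl-tRNA synthetase genes, which include ears-2 (1028), mars-1 (664), nars-1 (548) and kars-1 (518), had a peak in 17 of 32 cases (53.1%; adjusted exact p = 0.000163), a call that was lost with the 4270 IDR peaks of higher signal (odds ratio 1.82 instead of 4.33, adjusted exact p = 0.270, the highest of 8 alternatives). Against random lists matched on upstream distance and orientation, the odds ratio was 13.6 instead of 23.9 for the cytosolic ribosome, 6.97 instead of 11.2 for translation factors and 5.24 instead of 8.75 for oxidative phosphorylation. With each peak given only to the nearest gene start, these values were 4.95, 6.40 and 4.54, and that of the citric acid cycle was 16.9 instead of 29.4. The citric acid cycle had 68.5 with windows from 2000 bp upstream and 17.7 with the 4270 peaks of higher signal, and the cytosolic ribosome 37.1 with those peaks.

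**Figure D2:**
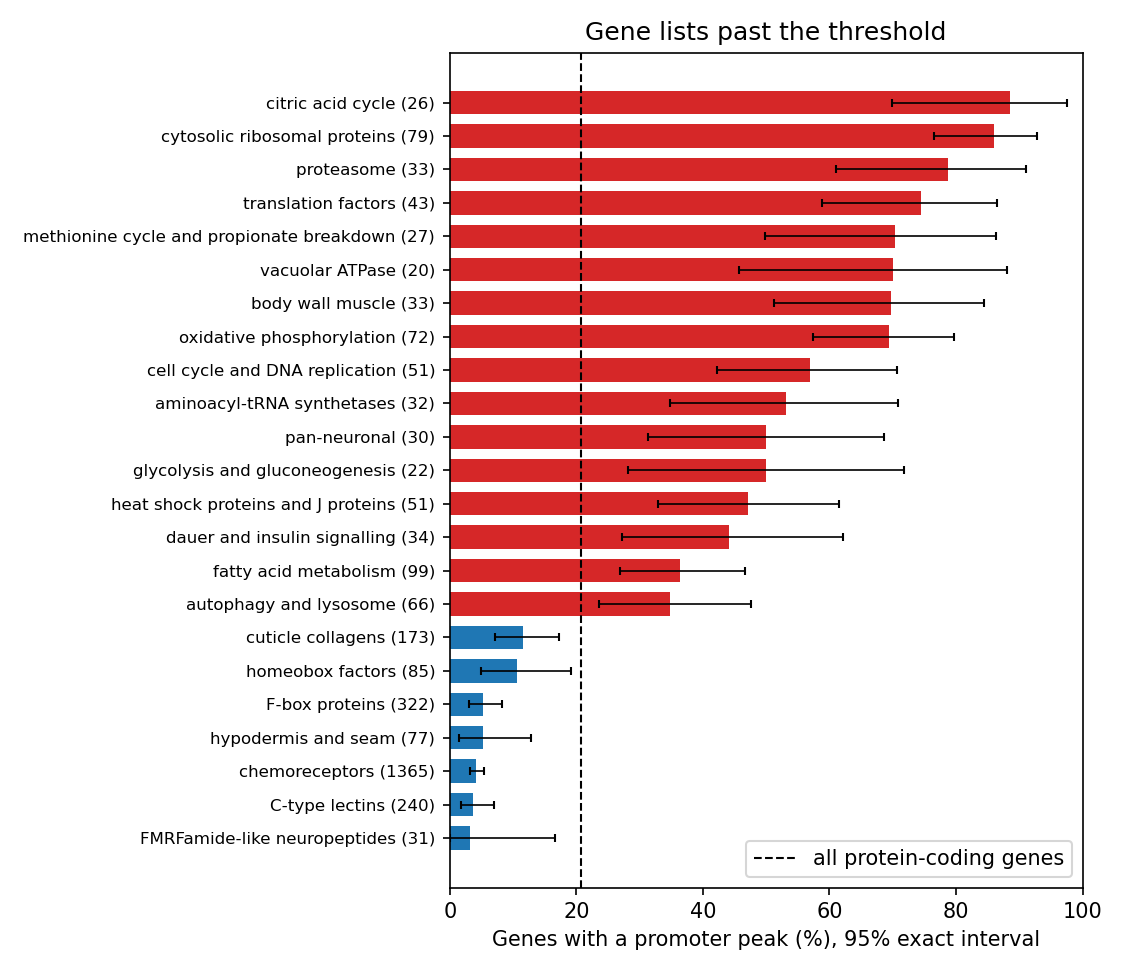
Percent of genes with a promoter peak (x axis) in each list past the threshold (y axis, number of genes in brackets), with 95% exact intervals as error bars; red bars are higher and blue bars lower than all other genes, and the dashed line is the share of all protein-coding genes. The lists range from 88.5% in the citric acid cycle to 3.23% in FMRFamide-like neuropeptides around an overall share of 20.8%.

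Protein turnover and organelle genes followed. Proteasome genes had a promoter peak in 26 of 33 cases (78.8%; adjusted exact p = 8.17e-12), with the highest signals at rpn-3 (1745), rpn-11 (948), rpt-2 (822) and pbs-1 (739). Vacuolar ATPase genes had one in 14 of 20 cases (70%; adjusted exact p = 1.04e-05), led by vha-12 (1253), vha-8 (1199), vha-1 (701) and vha-15 (681). Heat shock and J protein genes had one in 24 of 51 cases (47.1%; adjusted exact p = 0.000100). Those with the highest signals were the chaperone genes hsp-1 (2996), hsp-60 (2855), hsp-3 (2238) and dnj-13 (1844). In the autophagy and lysosome list, 23 of 66 genes had a peak (34.8%; adjusted exact p = 0.0177), among them lgg-2 (2978), epg-7 (2253), lgg-1 (1427) and epg-8 (827). That call was lost with 500 bp upstream (odds ratio 1.75 against 2.04, adjusted exact p = 0.106) and with the 4270 peaks of higher signal (1.91, adjusted exact p = 0.0790), and the latter gave vacuolar ATPase genes an odds ratio of 3.49 instead of 8.92. Windows from 2000 bp upstream gave vacuolar ATPase genes 15.5. The odds ratio of proteasome genes was 8.27 instead of 14.2 against matched random lists and 7.79 with each peak given only to the nearest gene start.

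Several lists of intermediary metabolism were higher too. The methionine cycle and propionate breakdown list had peaks at 19 of 27 genes (70.4%; adjusted exact p = 1.56e-07), with the highest signals at nhr-68, a receptor gene known to act in propionate metabolism (3250, a peak also in the window of H12C20.7, whose start is nearer), hphd-1 (722), hach-1 (612) and ech-6 (586). Fatty acid metabolism genes had one in 36 of 99 cases (36.4%; adjusted exact p = 0.00102). The strongest were at acs-2 (1375), ech-5 (1107), cpt-2 (975) and nhr-49 (905), which encodes a receptor that regulates fat metabolism. With the 4270 IDR peaks of higher signal alone, the odds ratio of this list was 1.16 (adjusted exact p = 0.704, the highest of 8 alternatives) instead of 2.19, and that of the methionine and propionate list 5.20 instead of 9.09. Glycolysis and gluconeogenesis genes had a peak in 11 of 22 cases (50%; adjusted exact p = 0.00462), including hxk-3 (602), pck-2 (554), gpd-2 (425) and fbp-1 (341). With windows from 2000 bp upstream its odds ratio was 7.29 instead of 3.82.

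Tissue and signalling lists were mixed. Body wall muscle genes had a promoter peak in 23 of 33 cases (69.7%; adjusted exact p = 9.25e-09), with mup-2 (673), unc-112 (546), mlc-2 (472) and unc-60 (469) highest. Pan-neuronal genes had one in 15 of 30 cases (50%; adjusted exact p = 0.000937), led by unc-14 (836), syd-2 (722), egl-21 (492) and ric-19 (489). Windows from 2000 bp upstream gave this list an odds ratio of 7.53 instead of 3.82. Cell cycle and DNA replication genes had one in 29 of 51 cases (56.9%; adjusted exact p = 7.51e-08), where cdc-48.1 was followed by pcn-1, the sliding clamp of replication (1921), lin-35, the retinoblastoma homologue (1404), and efl-1 (1352). In the dauer and insulin signalling list the count was 15 of 34 (44.1%; adjusted exact p = 0.00462), with akt-2 (738), daf-16, the FOXO factor gene (591), daf-10 (378) and tax-6 (373) highest. With a window of 500 bp upstream, the odds ratio of that list was 1.55 (adjusted exact p = 0.323, the highest of 8 alternatives) instead of 3.02.

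Chemoreceptor genes, the largest list, had a promoter peak in only 57 of 1365 cases (4.18%; 95% exact interval 3.18% to 5.38%; adjusted exact p = 4.37e-72). F-box genes had one in 17 of 322 cases (5.28%; adjusted exact p = 4.19e-14), with the highest signals at fbxb-85 (1517) and fbxa-90 (1352), and the latter peak is the same as that of efl-1. C-type lectin genes had one in 9 of 240 cases (3.75%; adjusted exact p = 2.90e-13), led by clec-126 (447), whose summit lay in no peak of replicate 1, and clec-53 (407). In the hypodermis and seam list 4 of 77 genes had a peak (5.19%; adjusted exact p = 0.000567), with sca-1 (450) and nhr-25 (386) highest. The share was 7.79% in each replicate list, where the odds ratio was 0.314 in replicate 1 and 0.315 in replicate 2 instead of 0.208, and windows from 2000 bp upstream gave 0.406. Cuticle collagen genes had one in 20 of 173 cases (11.6%; adjusted exact p = 0.00425), among them col-38 (1015) and col-71 (600). Homeobox genes had one in 9 of 85 cases (10.6%; adjusted exact p = 0.0397), with ceh-38 (1582) and ceh-20 (442) highest. A single FMRFamide-like neuropeptide gene of 31, flp-23 (251), had one (3.23%; adjusted exact p = 0.0244). The calls for homeobox and FMRFamide-like genes were lost against random lists matched on upstream distance and orientation (adjusted permutation p = 0.141 and 0.0934) and reached adjusted p of 0.290 and 0.178 over 8 alternatives. Against the matched lists their odds ratios were 0.545 instead of 0.450 and 0.172 instead of 0.127. Windows from 2000 bp upstream gave 0.631 and 0.292. With the 4270 peaks of higher signal, the calls for cuticle collagens (odds ratio 0.568 against 0.496, adjusted exact p = 0.0790) and for hypodermis and seam (0.354 against 0.208, adjusted exact p = 0.0682) were lost too, each the highest of 8 alternatives, while the odds ratio of chemoreceptors was 0.0667 instead of 0.154.

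Nuclear hormone receptor genes, the family to which NHR-71 belongs, had a promoter peak in 70 of 274 cases (25.5%; 20.5% to 31.1%; adjusted exact p = 0.102), which did not pass the threshold. Under 5 alternative settings it did, with odds ratios from 1.39 to 1.64, over 8 alternatives the adjusted p ranged from 0.00186 to 0.818, and with the 4270 peaks of higher signal the odds ratio was 0.917. The receptor genes with the highest signals were nhr-68 (3250, shared with H12C20.7), nhr-3 (1264), nhr-1 (1210), nhr-47 (1189) and nhr-48 (1085). Of 12 GATA factor genes, egl-27 (211) and elt-2, the main intestinal GATA factor gene (111), had a promoter peak (adjusted exact p = 1). The pharynx list had 2 of 34 (adjusted exact p = 0.0567, and from 0.0311 to 0.108 over 8 alternatives, of which the 4270 peaks of higher signal and matched random lists passed the threshold), the germline list 5 of 42 (adjusted exact p = 0.277), the intestine list 6 of 26 (adjusted exact p = 0.871), molting genes 6 of 50 (adjusted exact p = 0.251) and core histone genes 19 of 72 (adjusted exact p = 0.348). No vitellogenin gene of 6 had one, which allows a share of up to 50%. The other lists that did not pass had adjusted p from 0.246 to 1.

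The tagged gene itself, nhr-71, lies on chromosome X from 13747315 to 13751797 on the plus strand. Its promoter window held a peak from 13746768 to 13746932 with a signal of 278 (rank 2984 of the IDR set). Stronger peaks lay farther upstream, one from 13739026 to 13739691 (signal 1173) and one from 13744617 to 13745170 (signal 1117), outside gene bodies. In the 44.5 kb that span the gene and 20 kb to each side there were 19 IDR peaks, whereas windows of that size across the genome had a median of 3, and 0.297% of them had as many or more. Some of the 19 intervals overlap, such as 13741738 to 13742157 and 13741963 to 13742382, so they need not be separate sites. The summit of the first of that pair lay in no peak of replicate 1. At unc-119, whose mutation marks the strain and which lies on chromosome III from 10902641 to 10908935, no summit lay in the promoter window. The span of the gene and 20 kb to each side held 3 peaks, the median number for windows of that size, and 2 of these lay in its introns (signals 345 and 258).

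**Figure D3:**
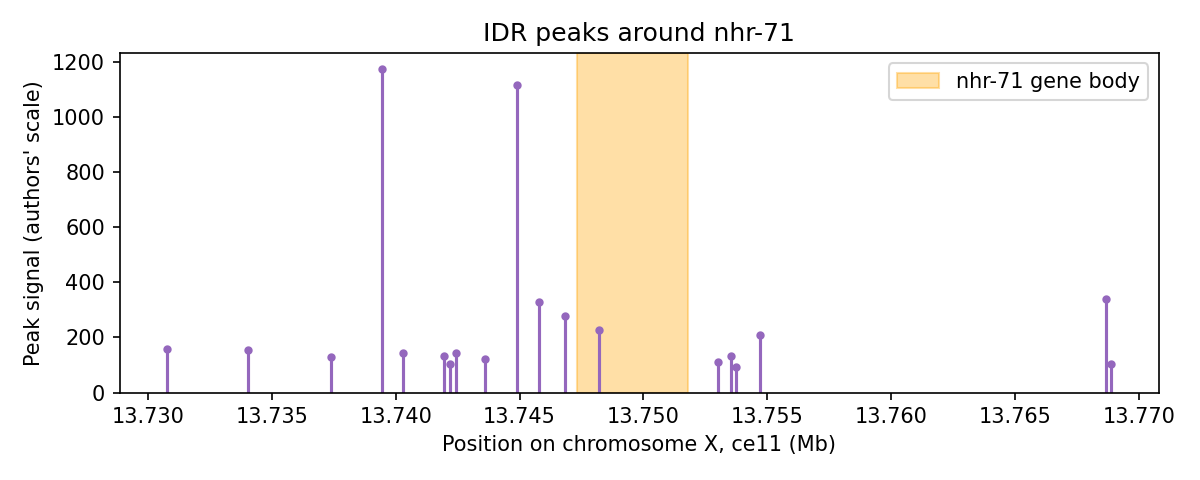
Signal (y axis, authors' scale) of the 19 IDR peaks within 20 kb of nhr-71 by summit position on chromosome X in ce11 (x axis, Mb); each line ends at 1 peak and the shaded part is the gene body. The 2 highest, at 1173 and 1117, lie upstream of the gene.

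Peaks were unevenly spread over the chromosomes. The share of protein-coding genes with a promoter peak was highest on chromosome III (28.5%) and lowest on chromosome V (15.9%). On the autosomes, genes in the middle part of the chromosome, where conserved genes are frequent, had a promoter peak in 25.5% of 9597 cases, and genes on the arms in 14.2% of 7645 (odds ratio 2.07, two-sided Fisher's exact test, p = 4.82e-77). The odds ratio was 1.94 in replicate 1 and 1.87 in replicate 2. Against random autosomal genes matched on the distance to the next gene upstream it was 1.32. Those random genes were drawn from whole autosomes, centres included, so 1.32 cannot be set beside the 2.07 against the arms. The X chromosome had 107 IDR peaks per Mb and the autosomes 80.6, a ratio of 1.32. By genes, the share with a promoter peak was 22.7% of 2731 on X and 20.5% of 17242 on autosomes (odds ratio 1.14, Fisher's exact test, p = 0.00769). This last difference did not hold in replicate 1 alone (1.07, exact p = 0.151), and with the 4270 peaks of higher signal the odds ratio was 0.910 (exact p = 0.130). Of the peaks on X, 33.1% lay in promoter windows, against 43.96% on autosomes. The median distance to the next gene upstream was 2123 bp on X and 826 bp on autosomes. A window of fixed length thus covers a smaller part of the upstream sequence on X. Genes on X were not compared with autosomal genes matched on that distance.

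Many sequence words differed in frequency between summits and flanks. The word TCTGCGTC occurred within the 100 bp centred on the summit in 6.55% of peaks and in 0.492% of the windows 300 bp to each side, a ratio of 13.3 (exact McNemar test, two-sided, adjusted exact p = 2.19e-115). The purine repeat GAGAGA occurred at 24.8% of summits and in 6.27% of flanks (ratio 3.95, adjusted exact p = 5.83e-230). The E-box CACGTG of basic helix-loop-helix factors had a ratio of 3.45, TGACGTCA of bZIP factors 3.23, the GC box GGGCGG 2.75, the CACCC box 2.68, the E2F site 2.25 and the E-box CAGCTG 2.15. Of the words bound by nuclear receptors, AGGTCA, the core recognised by many receptors, was at 3.74% of summits and 2.54% of flanks (ratio 1.47, adjusted exact p = 1.84e-05). The ratio was 1.32 in replicate 1 and 1.505 in replicate 2. AAGTCCA, the core of HNF4-type receptors, was at 0.480% against 0.732% (ratio 0.656, adjusted exact p = 0.0663). That word passed the threshold with the 4270 peaks of higher signal (0.486, adjusted exact p = 0.0396) and against windows matched on GC content (0.526, adjusted exact p = 0.00178), and over 5 alternatives that p ranged up to 0.360. The longer receptor word RGGTCAARGTCA, where R is A or G, was at 0 of 8540 summits and in 0.00585% of flanks, too rare to compare. The GATA core had a ratio of 1.12, which was 0.965 in the 4270 peaks of higher signal and 1.45 against promoter windows matched on GC content (adjusted exact p = 1.33e-33). Lower at summits were the acceptor word TTTTCAG (0.356), runs of T (0.408), the TATA box (0.5), the homeodomain word TAATTA (0.542, and 0.303 in the 4270 peaks of higher signal) and CCAAT (0.912), the last of which was not past the threshold with the 4270 peaks (0.907, adjusted exact p = 0.146). Of 22 words, 10 were higher and 5 lower.

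Summits were richer in G and C (43.3%) than their flanks (35.1% and 34.7%). Against promoter windows matched on GC content, the ratio of TCTGCGTC was 7.87, while the homeodomain word went from 0.542 to 1.12 (adjusted exact p = 0.241) and the calls for the CACCC box (adjusted exact p = 0.383) and runs of T (adjusted exact p = 0.0906) were lost. The ratio was 1.25 for the GC box, 1.29 for CAGCTG, 1.45 for the E2F site, 2.08 for TGACGTCA and 0.855 for the TATA box. Among all 2080 words of 6 bases, 829 were higher and 512 lower at summits. Those with the largest ratios were GCGCGC (6.40), ACGCAG (6.34), GACGCA (5.79), CGCGCG (5.21) and AGCGCG (5.15), and against the GC-matched promoter windows their ratios were 2.77, 3.93, 4.11, 2.38 and 2.57.

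**Figure D4:**
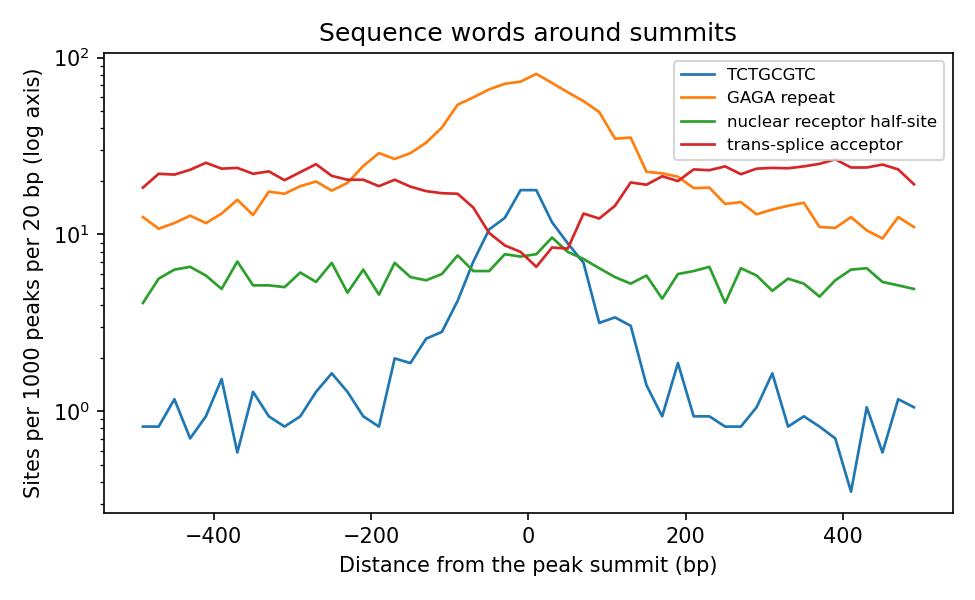
Number of sites per 1000 IDR peaks in bins of 20 bp (y axis, log scale) by distance from the summit (x axis, bp), for TCTGCGTC, the GAGA repeat, the AGGTCA core of nuclear receptors and the trans-splice acceptor word TTTTCAG. TCTGCGTC and the GAGA repeat are most frequent at the summit, where their ratios over the flanks are 13.3 and 3.95, and TTTTCAG is least frequent there.

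Genes for short stable RNAs often lay beside a peak. Of 612 tRNA genes, 305 had an IDR summit within 500 bp (49.8%; 95% exact interval 45.8% to 53.9%), against 9.26% ± 1.39 under circular shifts. The share was 39.9% of 346 snoRNA genes against 9.02%, 30.2% of 129 snRNA genes against 8.17%, 32.99% of 194 lincRNA genes against 15.5%, 24.1% of 261 miRNA genes against 9.001% and 21.99% of 7764 other ncRNA genes against 9.47%. Pseudogenes were less often near a peak (4.42% of 2128 against 15.6%), as were piRNA genes (3.31% of 15363 against 6.98%). For these 8 types the adjusted two-sided permutation p was 0.0025, and the replicate lists gave the same calls. Within 250 bp the ratio over shifts was 8.91 instead of 5.38 for tRNA genes, 5.65 instead of 3.70 for snRNA genes, 0.309 instead of 0.474 for piRNA genes and 0.158 instead of 0.283 for pseudogenes, and with the 4270 peaks of higher signal it was 7.03 instead of 4.42 for snoRNA genes. Antisense RNA genes had 23.0% against 13.3% (adjusted permutation p = 0.0178), a call that was lost within 250 bp (adjusted permutation p = 0.111), though the share there stayed above that under shifts. None of the 20 rRNA genes had a summit within 500 bp, which allows a share of up to 15%. Peaks near tRNA genes were 281 in number, with a median signal of 249 against 192 for all other peaks. Shifted positions fell in coding exons far more often than summits did, which can change the shares under shifts in a direction and to an extent not measured. Whether a summit near a non-coding gene belonged to the promoter of a protein-coding gene was not tested.

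**Figure D5:**
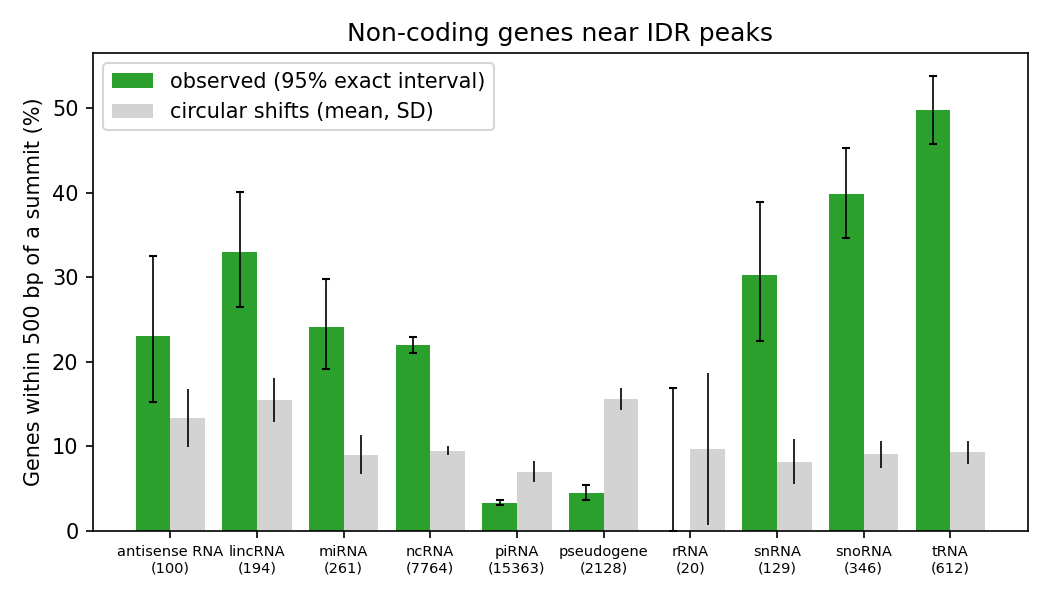
Percent of genes of each non-coding type within 500 bp of an IDR summit (y axis; number of genes in brackets on the x axis), with green bars for the observed share and its 95% exact interval and grey bars for the mean and SD of 1000 circular shifts. The tRNA genes stand highest at 49.8%, and pseudogenes and piRNA genes lie below their shifted values.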

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

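Only the rotation of bound genes along the gene order was chosen after the results were seen. Overlap of the replicates, the promoter share, the centres of autosomes against arms and the signal of promoter peaks kept their direction and their side of the threshold under each alternative run for them. Spearman's rho of 0.895 became 0.920 over the 4270 IDR peaks of higher signal, and Pearson's r on log2 signal was 0.923. With those 4270 peaks, 2671 genes had a promoter peak instead of 4152 and 4 lists were lower instead of 7, which follows in part from the smaller number of peaks. The odds ratio of X against autosomes turned from 1.14 to 0.910 with them, as did that of nuclear hormone receptor genes to 0.917 and the ratio of the GATA core over the flanks to 0.965. From single replicate lists the odds ratio of X ranged from 1.07 to 1.11. Replacing the flanks by windows at other promoter positions matched on GC content, which changes place and GC together, gave 477 higher words of 6 bases instead of 829 and turned the homeodomain word to 1.12. With each peak given only to the nearest gene start, GATA factor genes had an odds ratio of 1.01 instead of 0.762. For the values that turned direction, the cause was not tested. Of the lists past the threshold, 7 lost the call with the 4270 peaks, 3 with 500 bp upstream, and 2 each with 2000 bp upstream, nearest starts and matched random lists. Within 250 bp 8 non-coding types passed instead of 9. No list lost it in a single replicate list or under rotation. Read depth is unknown, so what it limits cannot be stated, and with 2 replicates the spread between them is imprecise for single genes. No paired analysis was possible because there was 1 group.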

Other observations

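The tests in this part were chosen after the results were seen, except the windows matched on GC content. Those windows were planned as an alternative, but their use to test GC content as an explanation was set afterwards. Gene-name families of at least 10 genes, most of them outside the fixed lists, gave further groups. Of 113 tested with Fisher's exact test and Benjamini-Hochberg adjustment, 16 had promoter peaks more often than other genes and 9 less often. Of these, 11 and 3 also passed when bound genes were rotated along the gene order, which allows for clusters of neighbours. Nucleoporin (npp) genes had a promoter peak in 17 of 26 cases (65.4%, adjusted exact p = 0.000115), with npp-3, npp-8 and npp-14 highest. Mitochondrial ribosomal proteins of the large subunit (mrpl) had one in 21 of 41 cases (adjusted exact p = 0.000346) and of the small subunit (mrps) in 14 of 29 (adjusted exact p = 0.00763). RNA polymerase II subunit (rpb) genes had one in 9 of 11 cases (adjusted exact p = 0.000493), Integrator subunit (ints) genes in 8 of 11 (adjusted exact p = 0.00351) and genes of the secretory pathway (sec) in 11 of 19 (adjusted exact p = 0.00450). None of 56 ligand-gated ion channel (lgc) genes had one, which allows a share of up to 5.36% (adjusted exact p = 0.000115), although the list of replicate 1 placed a peak at 5.36% of them. None of 29 cuticlin-like (cutl) genes had one (adjusted exact p = 0.0153).

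Sequence words differed with peak signal. When the IDR peaks were split by signal into 4 groups of 2135, TCTGCGTC was at 10.1%, 7.40%, 5.39% and 3.33% of summits from the strongest to the weakest group (first against last, Fisher's exact test, odds ratio 3.26, p = 3.91e-19). GAGAGA went from 31.0% to 17.8% (exact p = 1.72e-23) and the E-box CACGTG from 8.48% to 4.73% (exact p = 9.72e-07). The GATA core went the opposite way, from 17.1% in the strongest group to 28.0% in the weakest (odds ratio 0.530, exact p = 1.49e-17). The nuclear receptor core AGGTCA was at 3.33% and 4.17% (exact p = 0.171). The difference between words was not tested.

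The crowding of 19 IDR peaks around nhr-71 has a candidate technical explanation in the strain, since extra copies of the tagged transgene could raise the background over the inserted segment. Peaks of the most common width, 420 bp, were 12 of the 19 at the locus (63.2%) and 40.7% of all others, an odds ratio of 2.5 (Fisher's exact test, p = 0.0602). With 19 peaks, and with the extent and copy number of the insert not given in the sources used here, extra copies cannot be told apart from binding at this locus. No biological explanation was tested, because the design has 1 group.

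Peaks at housekeeping genes could come from signal that spreads along highly transcribed gene bodies. There were 168 summits within 200 bp on either side of the starts of the 710 genes in lists above background. Of these, 14.9% lay downstream, in the gene (exact binomial test, 95% interval 9.87% to 21.2%, p = 2.73e-21). Most of these summits thus lay ahead of the annotated bodies. Promoter peaks of all genes did so too, with 91.5% upstream of the nearest start over the whole window, and this was known beforehand. That window reaches farther upstream than 200 bp, so the 91.5% cannot be set beside the 14.9%. Because the place of promoter peaks was known, the 14.9% does not decide whether spread adds to the peaks of these genes. Counts in coding exons outside promoter windows decide nothing, since the 8 summits there were 1.11 times as frequent as in other genes (exact binomial test, p = 0.704) and 0.106 of the number under circular shifts, close to the 0.0944 of all genes together. Only summits were counted here, although an interval can be broad, as at icl-1, where it covers the whole gene. How often intervals cover gene bodies was not tested. For tRNA genes spread was not tested, and transcribed sequence ahead of annotated starts of trans-spliced genes was not told apart. Reads shared between tRNA copies could also give peaks. Of 143 tRNA genes with no identical copy, 30.1% lay near a summit, against at most 17.5% under shifts. This cannot exclude shared reads, because nearly identical copies count as no copy and a summit nearby may belong to a neighbouring gene. Copies may add to the tRNA pattern, as the share was 55.9% of 469 genes with a copy (Fisher's exact test, p = 6.69e-08). Signal that any antibody gives at open, active promoters stays open too, because the control and other factors were not analysed here, and no biological explanation was tested.

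The frequency of TCTGCGTC at summits might reflect their GC content or repeated sequence. Against promoter windows matched on GC content its ratio was 7.87 (adjusted exact p = 1.50e-95), and leaving out sites whose sequence with 6 bases on each side occurs more than once in the genome gave a ratio over the flanks of 15.3 (exact McNemar test, p = 7.70e-118). These values argue against GC content, and against exact copies of the sequence around the word, as the whole cause. Of the 559 summits with the word, 537 kept a site after the exact copies were left out. Diverged copies of a repeat count as single sites, so repeated sequence of that kind was not tested. Whether the word marks NHR-71 or accessible promoters in general stays open as a hypothesis, since no other factor was analysed here and no biological explanation was tested.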
